A study of Mus musculus with 8 samples.

How the data were processed

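Capped nascent RNA was profiled in frozen liver of C57BL/6J mice by PRO-cap, a run-on assay that sequences the 5′ ends of capped RNA still being made and so marks sites where transcription starts. The labels describe 8 samples, 4 from old mice of 22 to 25 months and 4 from young mice of 2 to 4 months, with 2 females and 2 males at each age. The submitters' processing notes name cutadapt 2.10, BWA 0.7.10, SAMtools 1.1, bedtools 2.27.1-65 and HOMER, and the builds hg19, GRCm38 and mm10, without saying which tool did which step. How peaks were called, and how cryptic peaks inside genes were told from annotated starts, is not given in the sources used here.

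The values come from 4 deposited peak lists, a larger and a stricter one for each age, all of intervals of 150 bp. Each larger list carries 1 fold per peak, a ratio that the authors deposited. The 2 stricter lists carry a score of 0 in every deposited row, so they were used for positions only. Their deposited names mention 10 RPM, 10 FC, NoInt and mm10, of which NoInt is not explained in the sources used here, and coordinates are given here 1-based in that build. Every row of the 4 lists has a plus sign in the strand column, which was read as a placeholder, and no result uses the strand of a peak. The labels tie each larger list to all 4 samples of its age, and the lists hold 1 pooled value per peak. The names of the larger lists carry OF and YF, marks that the labels otherwise use for files of the female samples, while files of the male samples carry OM and YM. Which libraries were pooled is not given in the sources used here, so the folds and reads may stand for females alone or for both sexes, and ages could not be compared against a spread between animals.

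The deposited folds were solved for the reads behind them. Each of the 976 old and 425 young folds equalled a scaled whole read count plus 1, over a scaled whole read count of the other age plus 1, within 1e-07 reads and with counts up to 1000 tried on the other side. Each value had 1 such solution. The value of 1 read was 8.55 times the added constant on the old side and 8.15 times on the young side. If both sides were scaled to the same total with the same constant, the old side had 0.953 times the depth of the young side. How the sides were scaled is not given in the sources used here. The total depth of either side is unknown. Ratios of reads were scaled by this relative depth and carry 95% Clopper-Pearson intervals, which cover counting error only. Where the other age had 0 reads, the ratio was computed against a floor of 3 reads on that side and is given as a lower bound, which corresponds to a one-sided 95% limit and is used wherever a bound for such a peak is given or counted. On simulated folds made at other depths, the solution returned the right pair of counts for 100% of 976 values in an old-like list and 100% of 425 values in a young-like list. For values moved at random by up to 1%, it returned a solution for 0% of either list.

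Peaks were assigned at their centre to the genes, exons, coding sequence and UTRs of GENCODE M21, which is on GRCm38, the assembly of mm10. A protein-coding gene holding the centre on either strand was a host gene. Relative position ran from 0 at the start to 1 at the end of the host gene. For a peak in several host genes, a gene that put it beyond the middle was preferred, then the longest. Lists were compared by overlap of at least 1 bp. The design set these comparisons before the data were examined, together with 18 gene lists of liver cell types and pathways. No test of age was made, because each age has 1 pooled list.

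Chance levels were described with random draws. Peaks were placed 1000 times at random in the open part of their own host gene, and distances were read from 100 of these placements. The open part lay beyond the middle of the gene and at least 3577 bp from any annotated transcription start, the smallest distance in the 4 lists. The restriction to the part beyond the middle was added after the positions of the peaks had been seen. Of 21924 protein-coding genes, 15820 had an open base and formed the background for gene lists. The peak lists hold no expression values, so random genes were not matched on expression. For each gene list, 10000 random gene sets with as many genes in each of 20 bins of gene length were drawn, and a list was called above chance when its count exceeded 97.5% of them. On 12000 simulated genes, 16 of 20 enriched sets and 8 of 280 others were called this way. The fixed gene lists had only 4 to 33 open genes each. The share of simulated sets called need not hold for lists this small, so an enriched list can be missed. Another 2 lists, of leukocyte and of hepatocyte genes, were written after the host genes with the most and highest peaks had been seen, left those genes out, and had their predictions set before their counts were known.

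The text names the 10 host genes with the most peaks and the host genes of the 10 highest folds in each larger list, and the 10 host genes with the most peaks in the stricter old list. It also covers every host gene of the stricter young list, members of the fixed gene lists that host a peak, except 1 that is not reported here, and up to 10 genes hosting peaks at both ages. Genes that host peaks of the 2 later lists, and the few others said to be so, were named after their values were seen. Alternatives joined neighbouring peaks within 500 bp or 5 kb, kept the peaks with the higher folds or more reads, or kept those with 0 reads at the other age. Others changed the overlap, the exon and start annotation, the host genes counted and the matching or weighting of random genes, and kept 1 peak per host gene. Results on sequence and repeats at the peaks need a genome sequence and were not made. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the Reactome sets came with fgsea 1.28.0.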

Results

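The data describe cryptic transcription start sites, that is, capped nascent RNA 5′ ends inside genes and away from annotated starts, in a study of liver from 4 old and 4 young samples. They consist of 1 larger and 1 stricter list of peaks for each age. The larger lists hold peaks with a deposited fold of at least 10 for 1 age over the other, so old-list peaks had the higher deposited value in old liver and young-list peaks in young liver. Peaks of the larger old list rested on a median of 159.5 reads from the old side, with quartiles of 107 and 280 and a range of 3 to 4412. Peaks of the larger young list rested on a median of 162 reads from the young side, with quartiles of 109 and 268 and a range of 4 to 7704. At the peaks with the fewest reads counting error alone leaves the direction open, and the window and strand over which reads were counted are not given in the sources used here. Whether the larger lists pool both sexes or females alone is not settled by the labels and list names. There are no replicate values in the lists, and intervals cover counting error only.

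The first comparison asked where capped starts inside genes were gained in old liver and where in young liver. The larger old list held 976 peaks in 608 protein-coding host genes, and the larger young list held 425 peaks in 304. Among the highest folds in old liver were those in Nfatc1, Sox5, Runx2 and Ikzf1, which encode transcription factors, and in Stk3, which encodes a kinase. Nfatc1, a calcium-responsive regulator of lymphocyte genes, held 9 old-list peaks and 0 young-list peaks. Young liver carried its highest folds in Rap1a, Ugcg and BC053393, and most peaks per gene in Rora, a nuclear receptor of the circadian and metabolic programmes of liver, with 5 peaks.

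The highest peak of the old list lay in an intron of Nfatc1 (ENSMUSG00000033016.16) on chromosome 18, from 80614874 to 80615023. It had 4412 reads on the old side and 0 on the young side, at least 1544-fold higher in old liver. Its centre was 5974 bp from the nearest annotated start, which belongs to the same gene, at 80608975. A neighbouring interval from 80614975 to 80615124 overlapped it and had 1619 reads against 0, so the pair can share reads. Of the 9 Nfatc1 peaks, 7 had 0 reads on the young side, and the stricter old list held 7 peaks in the gene. The remaining pair of larger-list peaks had 977 reads against 22 and 310 against 9.

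**Figure D1:**
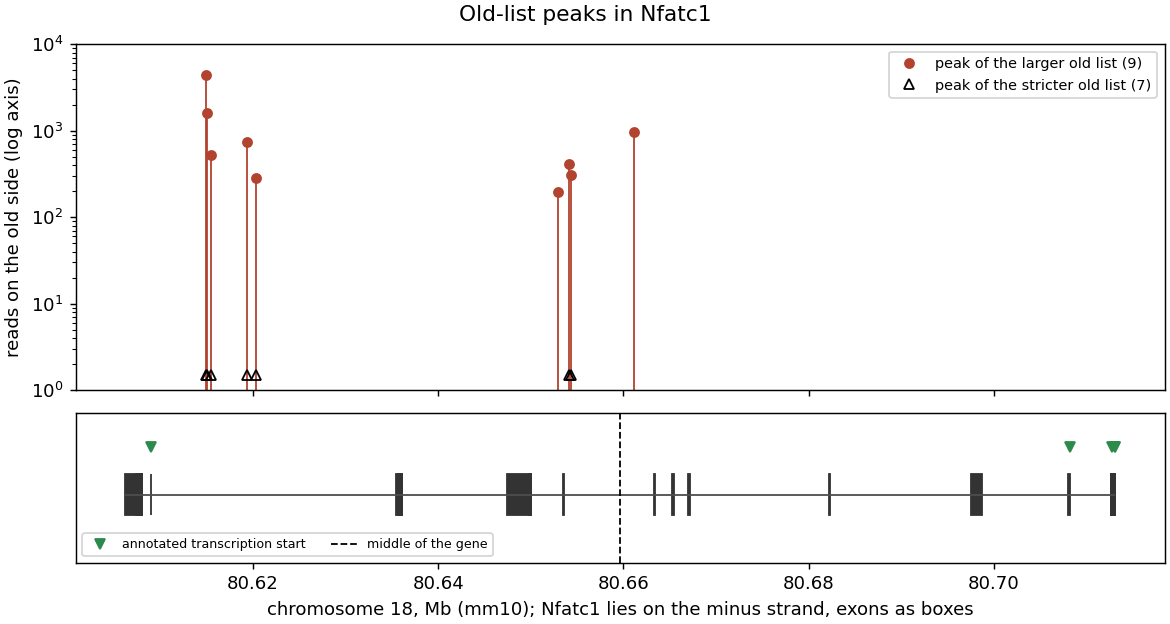
Old-list peaks along Nfatc1 on chromosome 18 (mm10, Mb). The upper panel gives the reads on the old side on a log axis for the 9 peaks of the larger list, from 194 to 4412, and marks the 7 peaks of the stricter list as triangles; the lower panel shows annotated exons, transcription starts and the middle of the gene, which is transcribed from right to left.

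Other high old-list peaks had 0 reads on the young side. In introns of 3300002I08Rik, Sox5 and Stk3 the reads on the old side numbered 1503, 1448 and 1232, at least 526-fold, 507-fold and 431-fold higher in old liver. Runx2, a regulator of bone development, had 1020 reads at 1 peak, at least 357-fold higher. Ikzf1, which encodes the lymphoid factor Ikaros, had 860 reads, at least 301-fold higher. The peak in Pigr, the receptor that carries polymeric immunoglobulin across epithelia, lay in a coding exon on chromosome 1 from 130848982 to 130849131, with 661 reads and a ratio of at least 231. Of the 10 highest old-list peaks, 1 lay in no protein-coding gene, in an intron of the non-coding gene Gm26839 with 740 reads. All 10 overlapped a peak of the stricter old list.

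Several genes held runs of old-list peaks. Msra, a methionine sulfoxide reductase that repairs oxidised protein, held 12 peaks with 39 to 670 reads, and 9 remained as separate loci after intervals within 500 bp were joined. Foxp1, a transcription factor of lymphocyte development, held 9 peaks at 7 such loci, Anks1b 8 at 6, and the proton channel gene Hvcn1 8 at 4. Stk3 and Elmo1 held 6 peaks at 5 loci, Snx29 and Celf2 6 at 4, and Pde4b 6 at 3. In all, 196 host genes of the old list and 75 of the young list held 2 or more peaks.

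The highest young-list peak lay in an intron of Rap1a, a small GTPase gene, on chromosome 3 from 105739972 to 105740121. It had 495 reads on the young side and 0 on the old side, at least 157-fold higher in young liver. Ugcg, which encodes the enzyme of the first step of glycosphingolipid synthesis, had 457 reads against 0 in a UTR, at least 145-fold higher. The peaks in BC053393, Zfpm1, Kcnn2, Ppp2r5e, Ptprg, Btbd7, Klhl2 and Apba2 had 278 down to 180 reads against 0, with lower bounds from 88.3-fold to 57.2-fold. The Zfpm1 peak also lies within the longer annotated gene Gm20388, which held 3 young-list peaks in all. Of these highest young-list peaks, from Rap1a to Apba2, only the Zfpm1 peak overlapped a peak of the stricter young list. The stricter young list also has a peak in Klhl2, but at another position, from 64792811 rather than from 64790667. Behind Rora, the genes Rbfox2, Bmp2k, Elovl2, Nfib, Rad51b, Daam1 and Tnrc6a held 4 young-list peaks each, and Ptprd held 3. The young-list peak with most reads lay in an intron of Kank1, named after its value was seen, with 7704 reads against 589 and a ratio of 12.5 (95% interval 11.5 to 13.6).

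**Figure D2:**
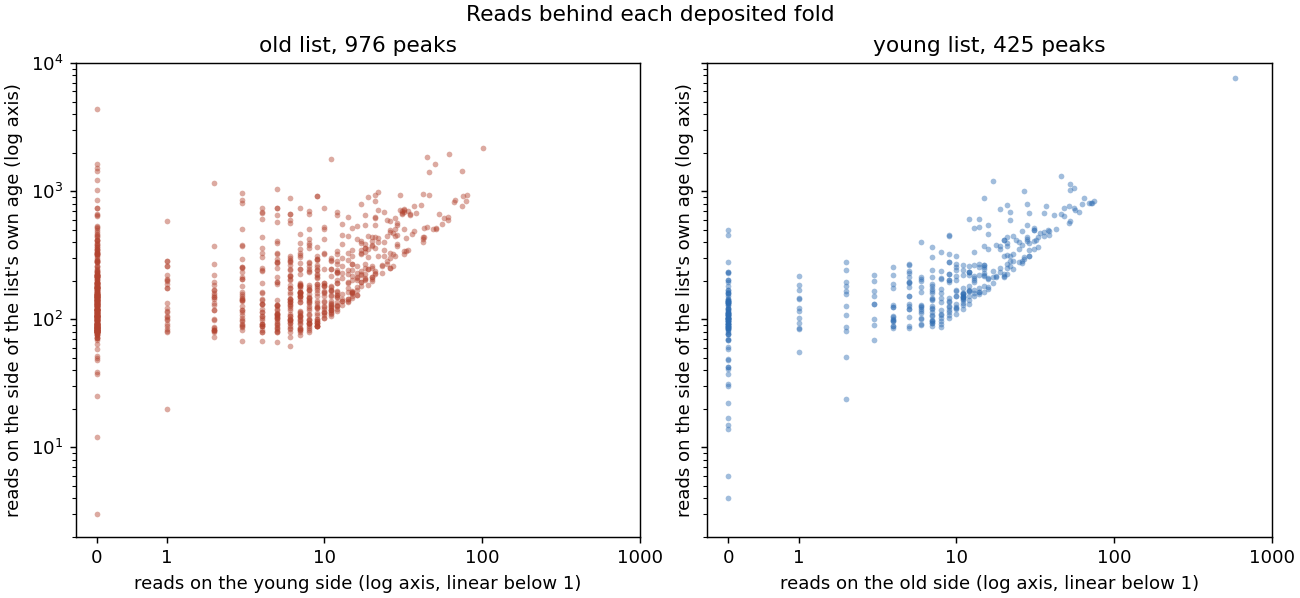
Reads behind the fold of each peak in the larger old list (left, 976 peaks) and the larger young list (right, 425 peaks). The vertical log axis gives reads on the side of the list's own age and the horizontal axis reads on the other side; the column of points at 0 holds 351 old-list and 107 young-list peaks.

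The 2 larger lists also differed in the share of peaks with 0 reads at the other age, which bounds the level there and does not show silence. In the old list, 351 of 976 peaks (36.0%, 95% interval 32.9 to 39.1) had 0 reads on the young side, and in the young list 107 of 425 (25.2%, 21.1 to 29.6) had 0 on the old side. These intervals, like the others on shares of peaks, treat each peak as separate and can be too narrow. Neighbouring peaks overlapped in 65 cases in the old list and 19 in the young list and can share reads. If both sides were scaled alike, the old side had 0.953 times the depth of the young side. With counting error, the lower bound of the ratio was under 10 for 271 old-list and 184 young-list peaks, among them Fah, Hnf4a and Nfia.

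The second comparison asked which gene groups hosted the peaks of each age. Young-list peaks lay in 6 of 23 open genes of the list of nuclear receptors and hepatocyte transcription factors, among them Hnf4a, Nfia, Nfib, Pparg and Rora. Random gene sets of the same lengths gave a median of 1 and a 95% range of 0 to 3, and 0 of the 10000 sets reached 6. These sets were not matched on expression, so genes expressed in liver could exceed them for that reason alone. Young-list peaks also lay in 3 of 26 open genes of hepatocyte secreted proteins, the carrier genes Ttr and Rbp4 and the hyaluronan-binding Itih2, against a random range of 0 to 1. In the old list the first group had 1 host gene, Tcf7l2, a Wnt pathway factor, and the second group 0.

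The young-list peaks of these genes were mostly of moderate ratio. The Rbp4 peak had 675 reads against 29, a ratio of 22.2 (15.3 to 33.4). The Ttr gene held overlapping intervals, of which 1 had 373 reads against 15, a ratio of 23.7 (14.2 to 42.8). In Hnf4a, a master regulator of hepatocyte identity, an intronic peak on chromosome 2 from 163559307 to 163559456 had 169 reads against 13, a ratio of 12.4 (7.05 to 23.7). In Nfia 1 peak had a ratio of 10.9 (8.40 to 14.5). Pparg had 111 reads against 0, at least 35.3-fold higher in young liver. Nfib held 4 peaks with 107 to 839 reads.

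The share of host genes from the list of nuclear receptors and hepatocyte transcription factors was 0.164% in the old list and 1.97% in the young list. The difference of old minus young of -1.81 percentage points lay outside the range of -0.822 to 0.493 given by pairs of random gene sets of the same lengths. For hepatocyte secreted proteins the shares were 0% and 0.987%, a difference of -0.987 against a random range of -0.329 to 0.329. These 2 lists had already been found above chance in young from the same host genes. The differences therefore largely restate that result and are not separate support for it. Over all 18 fixed lists, the same comparison put these 2 below, 0 above and the others within their random ranges. These ranges describe the 2 peak lists and do not carry the spread between animals.

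The remaining 16 fixed lists stayed within the random range at both ages, and the old list exceeded it for 0 of the 18. With as few as 4 open genes in a list, this does not show that enrichment was absent. Old-list peaks lay in 2 genes of fatty acid and lipid metabolism, the elongase gene Elovl6 and the hepatic lipase gene Lipc. They lay in 1 gene each of amino acid metabolism (Fah, the last enzyme of tyrosine breakdown), chromatin and transcription elongation (Chd1, with 3 peaks) and hepatic stellate cells (Col14a1). Single host genes were also found for liver endothelial cells (Cdh5, the vascular cadherin) and for senescence and inflammation (Nfkb1, with 4 peaks). Young-list peaks lay in 1 gene each of amino acid metabolism (Got1) and the circadian clock (Rora), the latter of which also belongs to the list of nuclear receptors and hepatocyte transcription factors. No member hosted a peak of either age for Kupffer cells and macrophages, cholesterol and bile acid metabolism, complement and acute phase, cytochrome P450 and drug metabolism, erythroid cells, glucose metabolism, lymphocytes and sex-biased liver genes. Of the 20 lymphocyte genes, 8 had an open base, so most could not host a peak.

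**Figure D3:**
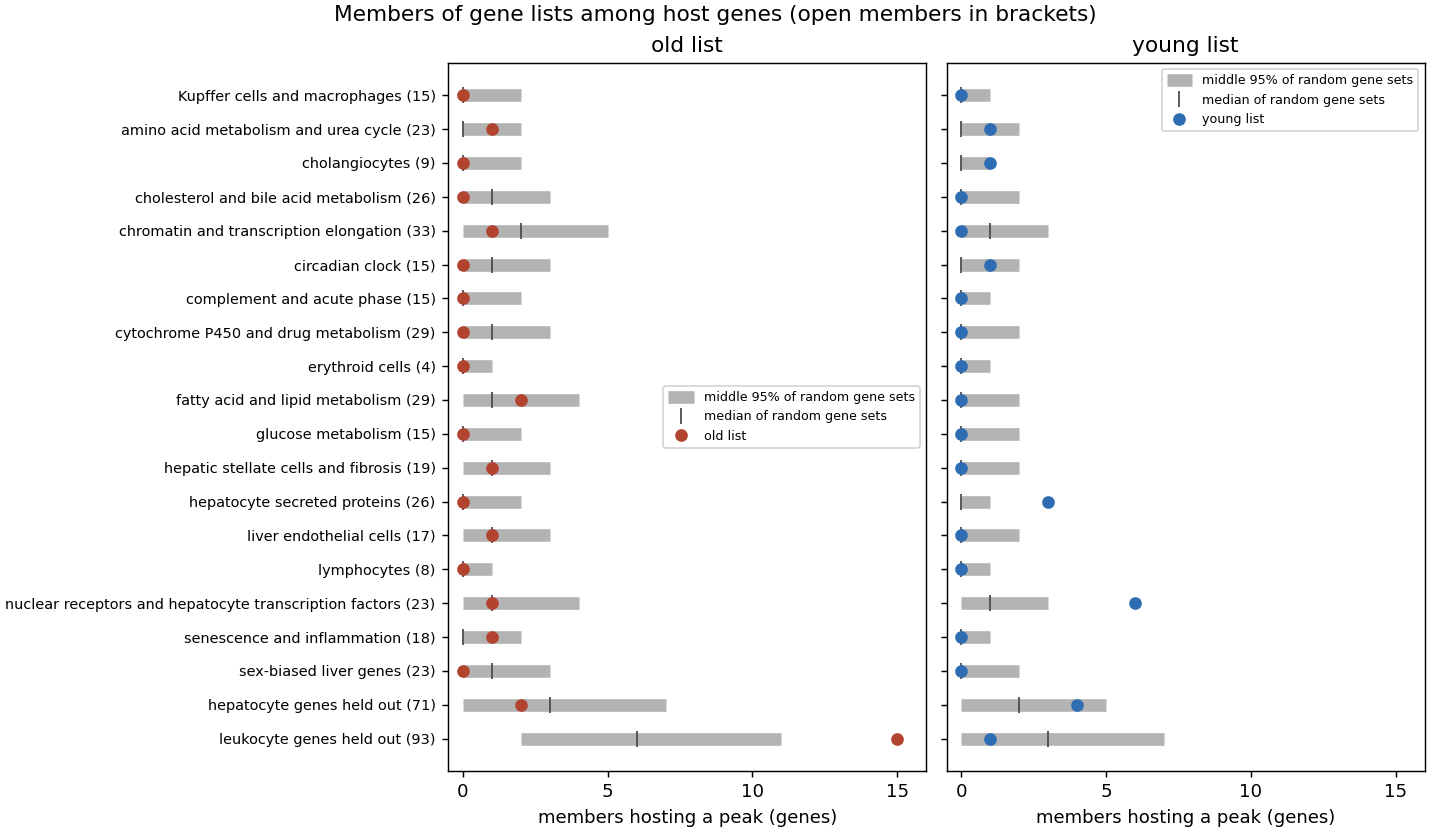
Members of 18 fixed gene lists and of 2 later lists (held out) that host a peak, for the larger old list (left) and the larger young list (right). Points give the number of host genes, grey bars the middle 95% and ticks the median of 10000 random gene sets of the same lengths; the points to the right of their bars are the nuclear receptor list (6) and secreted proteins (3) in young and the later leukocyte list (15) in old.

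The third comparison asked whether both ages used the same genes and positions. No old-list peak overlapped a young-list peak, and the closest centres of opposite lists were 761 bp apart. In part this follows from the lists, since the same interval cannot have a fold of at least 10 in both directions. Random placement within host genes also gave a median of 0 old-list peaks overlapping a young-list peak, with a range of 0 to 1. At the level of genes, 32 hosted peaks of both larger lists, against a random median of 23 and range of 15 to 32 for genes of the same lengths. Among peaks with 0 reads on the other side, a setting added later, 4 genes were shared. That setting left only 258 old-list and 97 young-list host genes, and no random range was drawn for it. Rad51b, a recombination repair gene, held 3 old-list and 4 young-list peaks, and the phosphodiesterase gene Pde4d held 2 and 3. Msra had 12 and 1, Foxp1 9 and 2, Nsmce2 5 and 1, Ano6 4 and 1, and Arhgef3 3 and 2. Adgrv1 had 1 and 3, Gm20388 1 and 3, and Sgms1 2 and 2. Gm20388 is annotated over 4434882 bp and spans other genes. Its old-list peak also lies in Ankrd11 and its young-list peaks in Zfpm1 and Rhou, where Ankrd11 and Rhou were named after the peaks were seen. It is counted among the 32 but does not show shared use of 1 gene.

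The fourth comparison asked where in the genes the peaks lay. At both ages most peaks were intronic, 837 of 976 in the old list (85.8%) and 367 of 425 in the young list (86.4%). Exons held 128 old-list peaks (13.1%, 95% interval 11.1 to 15.4) and 52 young-list peaks (12.2%, 9.27 to 15.7), intervals that overlap. Coding sequence held 51 and 15 of them, among them the old-list peaks in Pigr and Fah and young-list peaks in Tnrc6a. Only 11 old-list and 6 young-list peaks lay outside any annotated gene.

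In the open part of the host genes, random placement gave exon shares close to those seen. Of the 865 old-list peaks beyond the middle of their gene, 13.6% were exonic against a random range of 10.8% to 14.8%. For the 377 such young-list peaks, the exonic share was within the random range of 9.55% to 15.4%. With random positions in the whole host gene, a setting added later, the old and young shares were 1.46 and 1.44 times the random median and lay above the random range.

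Peaks were confined almost fully to the downstream part of genes. Of the old-list peaks in protein-coding genes, 865 of 915 (94.5%) lay beyond the middle of the host gene, as did 377 of 400 young-list peaks (94.3%). The choice of host gene could raise these shares for the 38 old-list and 11 young-list peaks that lay in several. The count rose from 15 old-list peaks between positions 0.45 and 0.5 to 61 between 0.5 and 0.55, and from 5 to 43 for the young list. The nearest annotated start was never closer than 3577 bp in the old list and 3579 bp in the young list, with medians of 13119 and 12872 bp. Edges this sharp at both ages are properties of the lists, and this confinement is not read here as a result. Beyond the middle, the median position of old-list peaks was 0.769 against a random range of 0.730 to 0.761, and with 1 peak per host gene, a setting added later, it was 0.767 and within 0.728 to 0.769. That of young-list peaks was 0.738, within 0.725 to 0.776.

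**Figure D4:**
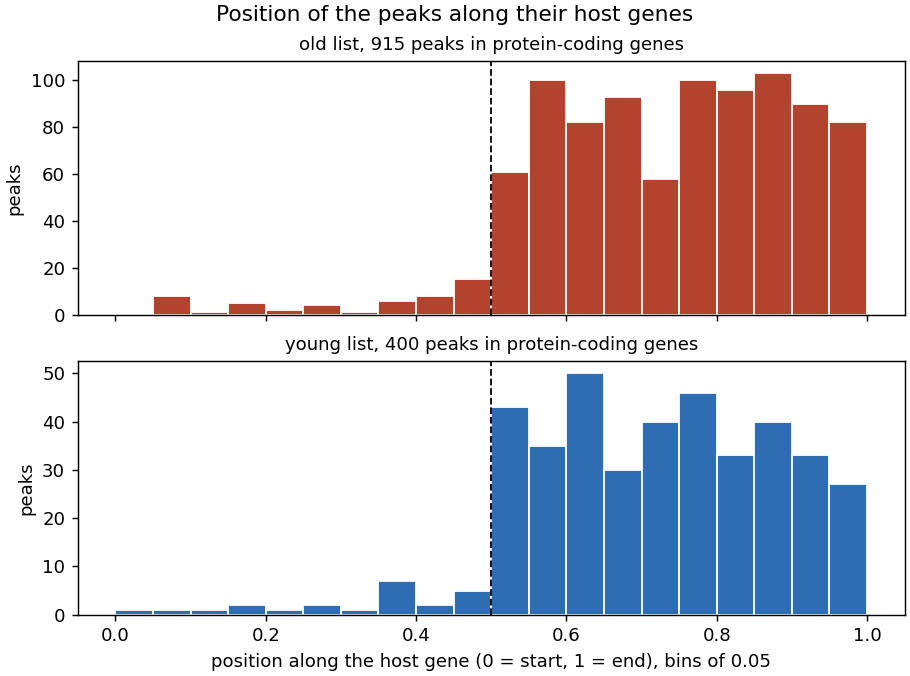
Number of peaks of the larger old list (top) and larger young list (bottom) by relative position along the host gene, in bins of 0.05 from 0 at the start to 1 at the end. The dashed line marks the middle of the gene, beyond which 865 of 915 old-list and 377 of 400 young-list peaks lie.

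Host genes of both ages were long. The median length was 88347 bp for the old list and 100496 bp for the young list, where random sets of open genes, drawn without regard to length, had medians of 25780 to 31735 bp and 24732 to 33422 bp. Random genes drawn in proportion to the length open to peaks, a setting added later, had medians of 134704 to 168787 bp and 134743 to 197100 bp, so by this measure the host genes were shorter than chance. Anks1b, Foxp1, Celf2 and Sox5 in the old list and Rora, Ptprd and Ptprg in the young list all exceeded those medians, while Hvcn1 with 8 old-list peaks spanned 35494 bp and Ttr 9042 bp.

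The fifth comparison asked which peaks stood in the stricter lists. The stricter old list held 216 peaks in 160 host genes, and the stricter young list held 10 peaks in 11 host genes. The stricter young peaks lay in Asap1, Dst, Enpp2, Fermt2, Klhl2, Ptdss1, Scara5, Socs4, Zfp235 and Zfpm1, the last of which overlaps Gm20388. The stricter old list held most peaks in Nfatc1 with 7, the Sry-box factor gene Sox5 with 4 and the Hippo kinase gene Stk3 with 4. Arhgef3, Igf1r, Msra, Pde4b, Tenm4 and Trio followed with 3 each, and Ankrd33b had 2. Of the stricter old peaks, 197 (91.2%, 86.6 to 94.6) overlapped a peak of the larger old list, 182 of them with the same coordinates. Of the stricter young peaks, 4 of 10 (40%, 12.2 to 73.8) overlapped a peak of the larger young list. The stricter lists shared 0 host genes between ages, where random genes of the same lengths shared 0 to 1.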

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

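Among these settings, the peaks with 0 reads on the other side, peaks at or above the median of reads, joining within 5 kb, matching on open length, genes open in any part, random positions in the whole gene, drawing by open length and 1 peak per host gene were chosen after seeing the data. Keeping the peaks at or above the median deposited fold left 488 old-list and 213 young-list peaks, by construction. Counting any base of a peak raised the exonic share of the old list to 16.6%. Starts of protein-coding transcripts only gave median distances of 17192 bp (larger old), 15781 bp (larger young) and 19060 bp (stricter old), since fewer starts were counted. Old-list host genes with 1 peak had a median length of 78910 bp. Peaks with 0 reads on the other side lay in 258 old-list and 97 young-list host genes, 4 of them shared, and peaks at or above the median of reads in 313 and 163. Random positions in the whole host gene put the exonic share at 1.46 (old) and 1.44 (young) times the random median and above its range, which the main setting did not. Drawing random genes in proportion to open length turned the length of host genes from above to 0.582 (larger old), 0.621 (larger young), 0.602 (stricter old) and 0.556 (stricter young) times the random median, by the construction of the draw. With 1 peak per host gene the median position of old-list peaks, 0.767, no longer lay above the random range. The overlap of old and young lists stayed at 0 with every overlap tried. The number of gene lists above chance stayed at 0 for old and 2 for young under the other matchings. No paired analysis was possible because the lists carry 1 pooled value per peak, and leaving out single replicates was not possible for the same reason. The share of peaks on the host strand, the 5′ end of a peak, and the sequence and repeat settings were not run, the first ones for want of a strand and the last for want of a genome sequence. Host genes on either strand were the main setting. Reads per peak limit the precision: 271 old-list and 184 young-list peaks have a ratio whose lower bound is under 10.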

Other observations

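The tests of list length, of loci, of host genes and of the read minimum were chosen after the results were seen, and those on the later gene lists were set before their counts were known.

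The fixed lists of lymphocytes and of Kupffer cells and macrophages had 0 old-list host genes, and a later, longer list of leukocyte genes had more than random genes. Of its 93 open genes, 15 hosted an old-list peak, against a random median of 6 and range of 2 to 11. They were the B cell factors Ebf1, Bach2 and Irf4, the T cell factors Bcl11b, Lef1 and Runx3, the signalling genes Fyn, Rasgrp1, Dapp1 and Nfatc2, and Bcl11a, Elf1, Ets1, Rel and Zeb2. The Rel peak, in an intron of this NF-kappaB gene, had 662 reads against 8, a ratio of 86.9 (95% interval 43.8 to 202). The Irf4 peak lay in a coding exon, with 141 reads against 4 and a ratio of 37.0 (14.1 to 138). The Bcl11b and Elf1 genes had peaks of 284 and 219 reads against 0, at least 99.4-fold and 76.6-fold higher in old liver. In the young list 1 gene, the phospholipase gene Plcg2, hosted a peak. The share of host genes was 2.47% in the old and 0.329% in the young list, a difference of 2.14 percentage points against a random range of -1.48 to 1.15. In the stricter old list 6 genes of the later list hosted a peak, Bcl11b, Dapp1, Elf1, Fyn and Rel from those above and Dock2, against a random range of 0 to 4. Most stricter old peaks are also in the larger old list, so this count is not separate support. In the stricter young list the later hepatocyte list and the 2 fixed lists above chance in young had 0 host genes. Random sets of its 11 host genes also had a median of 0 for each.

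Of 71 open genes of the later hepatocyte list, 4 hosted a young-list peak, namely Aldh1a1, Gldc, Mug1 and Slc38a4, and 2 an old-list peak, Lpin2 and Slco2b1. The random ranges were 0 to 5 and 0 to 7. On the Y chromosome the larger old list held 1 peak and the stricter old list 1, from 90806722 and from 90807563. Both lay in introns of Gm47283, near the distal end of that chromosome. These peaks are not read here as a sign of which sexes were pooled.

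A pattern to follow up is the contrast between immune genes in the old list and hepatocyte regulators in the young list. Matching random genes on the length open to peaks left the later leukocyte list at 2.39 times the random mean, which argues against length as the cause of the excess. The 15 leukocyte host genes are what more leukocyte transcription in old liver predicts. Their list was written after the top host genes, Nfatc1 and Ikzf1 among them, had been seen. The count therefore extends the pattern and does not separate its causes. A larger share of leukocytes in old tissue may be a candidate explanation, although levels of abundant leukocyte transcripts are not in the lists. Zeb2, Ets1 and Fyn are also expressed by other liver cells. The 4 young-list host genes of the later hepatocyte list lay above the random median and within the range, so hepatocyte transcription in young liver stays open. An effect of age within each cell type also stays open, and the 15 open Kupffer cell and macrophage genes and 8 open lymphocyte genes of the fixed lists hosted 0 old-list peaks, within their random ranges.

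The old list was longer, with 2.30 times as many peaks. A deeper old side would predict a depth well above the young side, and the relative depth was 0.953. This argues against depth as the cause if both sides were scaled to the same total, which is not known. Joining intervals within 5 kb left 1.94 times as many old as young loci, and counting each host gene once left 2 times as many. Split loci or crowded genes can thus account for part of the difference, but neither alone for all of it. Age itself stays open as an untested explanation, since each age has 1 pooled list and the spread between animals is unknown.

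The stricter lists differed more, with 21.6 times as many old peaks. If a read minimum alone had made them from the larger lists, every stricter peak would overlap a larger-list peak of its age. In old 19 of 216 did not and in young 6 of 10, which argues against a read minimum alone. Of the larger old-list peaks with a minimum of 200 reads, 176 of 376 (46.8%) stood in the stricter old list. For the larger young list 2 of 172 such peaks (1.16%) stood in the stricter young list. Peaks above the same read minimum were thus kept at unlike rates, so the 21.6 need not be a like-for-like contrast of age. A different set of pooled libraries or another filter behind the stricter lists may be the reason and was not tested.

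Among Reactome pathways, examined after the lists had been seen, 0 of 839 passed an adjusted threshold of 0.05 for either age against genes of the same lengths, with 21 for old and 19 for young before adjustment. On the 12000 simulated genes this threshold called 8 of 20 enriched sets and 0 of 280 others. The pathway test had fewer genes, with 218 old and 119 young host genes in a background of 4960. The simulated share need not hold for it, and an enriched pathway can be missed.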
